A study of Homo sapiens with 22 samples.

How the data were processed

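MicroRNA levels were measured in K562, an established human erythroleukaemia line, on Illumina miRNA BeadChips with total RNA prepared with Trizol and a single Cy3 channel. The series held 22 arrays in 11 groups of 2 arrays. Hemin, an inducer of erythroid differentiation in this line, was given for 0 h, 48 h and 72 h. EKLF, GATA1 or NFE2, transcription factors of the erythroid lineage, were overexpressed against a pcDNA3.1 vector control, or knocked down with siRNA against a control siRNA (siCON). Groups were taken from the labels. The titles of 1 EKLF and 1 pcDNA3.1 overexpression array lacked a replicate number, so no pairing of arrays was used there.

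Per the submitters' processing notes, the arrays were read with GenomeStudio 2010.2; the notes name no genome build. Each deposited scanner file held, for 1145 probes, the bead-averaged intensity without background subtraction, as the values showed, and a detection p-value against the negative controls of the array, per the file headers. Of the probes, 858 carried miRNA names and 287 candidate identifiers. Several miRNAs shared the probe in 11 cases, and 28 names came from older miRBase releases (ending in :9.1 or :11.0). The authors also deposited a table of intensity values on a linear scale. Checked against the scanner files, it was background-subtracted and scaled to one mean within each experiment (597.1 for hemin, 296.9 for overexpression, 249.1 for siRNA). In that table, 18 of 22 columns were a straight-line function of their own array within 0.1 intensity units. The columns of EKLF overexpression array 1, GATA1 overexpression array 2 and both NFE2 overexpression arrays were identical to that of GATA1 overexpression array 1, which made 5 identical columns. The scanner files were therefore used throughout and the table only as an alternative, without the 4 columns that did not match their own array. This left 1 array each for EKLF and GATA1 overexpression and none for NFE2 overexpression.

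Signals were background-corrected with the normexp model using the detection p-values (offset 16), quantile-normalized over the 22 arrays and put on the log2 scale (limma 3.58.1 in R 4.3.3; tables with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3). Quantile normalization gives every array the same distribution, so changes are relative to the other probes of the array and a change in the total amount of miRNA cannot be seen. The 867 probes with a detection p under 0.05 on both arrays of at least 1 group were tested. A limma fit with 11 group means left 11 residual degrees of freedom (prior 2.1), with a typical residual SD of 0.102 log2. Each of 9 comparisons of 2 groups and 3 differences between an overexpression and an siRNA effect was tested two-sided with the moderated test of limma, with Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05. Errors after ± are the SE of the fit with n = 2 arrays per group unless given as SD. The fit has 1 residual variance per probe, shared by all 11 groups, so an SE does not follow the spread within the groups compared. For miR-222 it was 0.099 at 72 h against 0 h of hemin, where the SDs were 0.012 and 0.012. It was also 0.099 with NFE2 siRNA, where the SD was 0.297 in siCON. The SE can thus be too small for groups with noisy arrays and too large for others. For arrays, the number of replicates limits the precision. Nothing in the labels says that the arrays of a group came from separate cultures, so each p measures the spread between arrays, which may be technical.

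Where a probe was below background on both arrays of one group (detection p not under 0.05), its fold change is given as a bound. Each array of that group was then set to the lowest value of a detected probe on that array, or to the probe's own value if higher. Such a bound holds on the quantile-normalized scale only. On dim arrays, normalization can spread small raw differences into large ones, so it need not hold for the raw change. A probe detected on 1 of the 2 arrays of a group kept its fitted log2 value, and the text says so. No fold is given for a probe below background in both groups, or where the bound lay under 1.

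Lists of 19 miRNA families, clusters and cell types were tested in each of the 9 comparisons with camera (limma, preset correlation of 0.01) and adjusted over all 171 tests, with an estimated correlation beside it. They were miRNAs reported to rise or to fall in erythroid maturation, the miR-23/27/24 clusters, the miR-17-92 cluster and its paralogs, the let-7, miR-15/16, miR-181, miR-30 and miR-29 families, megakaryocyte and myeloid, lymphoid and pan-leukocyte, hypoxia and stress, the chromosome 19 cluster, the chromosome 14 imprinted cluster, the X-linked cluster from miR-506 to miR-514, and, as markers of other cell types, epithelial, striated muscle, neural and liver miRNAs. Some miRNAs are in several lists, such as miR-223, miR-15b and miR-363.

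The comparisons, tests, lists and naming rule were fixed before the data were examined. Named miRNAs were the 10 largest rises and falls among miRNAs past the threshold whose arrays did not overlap between groups (5 and 5 for 72 h against 48 h and for the differences), a fixed panel of 11 (miR-451, 144, 486-5p, 210, 221, 222, 223, 155, 23a, 27a and 24), and up to 4 members of each list described. Probes without a miRNA name were counted but not named. Alternatives fixed beforehand were no background correction (values floored at 16), an offset of 50, median scaling on the 141 probes detected on all arrays, cyclic loess, no filter, a stricter filter (detection p under 0.01 in the groups compared), each experiment normalized alone (for the differences, the fit without the hemin arrays), eBayes with trend and robust options, the authors' table, a replicate block for hemin and siRNA, leaving out each array, and camera with an estimated correlation. With each experiment normalized alone, the fit also took its residual variance from the arrays of that experiment only. Calls gained or lost there may come from either change. A block on the chip was not run, as no file gave a chip barcode. After the data were seen, a filter to probes detected in both groups and a fit without the 3 dimmest groups were added.

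The pipeline was tested on simulated data with the same groups. All groups were drawn from the 0 h profile, and only probes above background were changed, in the 48 h group. It recovered 86% of 100 probes changed 2-fold and 100% of 100 changed 4-fold, with 26 false calls among 212 calls over 823 tested probes, and made 0 calls in a contrast without change. The real groups had unlike profiles and mean signals from 102.6 (siCON) to 677.1 (72 h of hemin). These rates may therefore not hold for the dim groups or for probes near background. The median estimates were 0.74 for 2-fold and 1.69 for 4-fold changes on the log2 scale, below the simulated changes; the cause was not tested. Correlation between pairs of comparisons that share a control was set against 100 simulated draws without any effect.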

Results

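The data were miRNA signals from 22 arrays of K562 cells, with 2 arrays in each of 11 groups: untreated cells (0 h), cells given hemin for 48 h or 72 h, cells overexpressing EKLF, GATA1 or NFE2, their pcDNA3.1 vector control, cells given siRNA against EKLF, GATA1 or NFE2, and their siCON control. Mean raw signal over 1145 probes ranged from 91.2 to 687.8 per array, and 386 to 697 probes were detected. In the hemin experiment it was 657.2 and 605.1 at 0 h, 554.8 and 532.5 at 48 h, and 687.8 and 666.4 at 72 h. Among the overexpression arrays it was 127.0 and 144.1 for EKLF, 338.2 and 306.9 for GATA1, 541.8 and 512.7 for NFE2, and 468.0 and 415.4 for pcDNA3.1. Among the siRNA arrays it was 114.0 and 91.2 for siCON, 440.0 and 388.2 for EKLF, 532.4 and 499.0 for GATA1, and 170.2 and 141.5 for NFE2. The groups thus differed in brightness, and the EKLF overexpression, siCON and NFE2 siRNA arrays were the dimmest. On EKLF overexpression array 1, the 5 brightest probes held 67.5% of the signal above background. Arrays of a group correlated at r of 0.994 to 0.999 over the log2 signals of all probes, and 141 probes were detected on all arrays. Rank correlations within a group ran from 0.848 to 0.989. They were lowest for siCON (0.848), the control of all siRNA comparisons, and for NFE2 siRNA (0.859). Changes are log2 values relative to the other probes of each array, with ± giving the SE of the limma fit. Bounds ("at least") are given where a probe was below background on both arrays of a group. They hold on the normalized scale only.

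Among the brightest normalized signals of untreated K562 cells were those of miR-544 (14.07), miR-92a (13.81), miR-324-5p (13.59), miR-486-5p (13.34), miR-20a (12.82), miR-25 (12.66) and miR-21 (12.38); these were read off after the values were seen. miR-544 was among the 5 brightest probes on every array except those at 48 h and 72 h of hemin, and miR-324-5p on every siRNA array. The raw signal of miR-544 was 18659 on 0 h array 1 and 17835 on EKLF overexpression array 1. The mean signals of these arrays were 657.2 and 127.0, so its rank need not reflect its abundance in untreated cells. miR-92a and miR-20a belong to the miR-17-92 cluster, and miR-486-5p is abundant in erythroid cells. The myeloid miR-223 stood at 11.73 ± 0.20 (SD, n = 2) and the erythroid miR-451 at 5.88 ± 0.04 (SD, n = 2). The siCON cells were near the untreated cells for miR-223 (12.08) and miR-486-5p (12.35). In the pcDNA3.1 cells these were 6.47 and 8.14. The 50 brightest probes of untreated cells had a median of 11.40 there, 11.30 in siCON, 7.78 in pcDNA3.1, 6.60 with EKLF, 6.93 with GATA1 and 7.98 with NFE2 overexpression. All 4 groups of the overexpression experiment, the control included, thus had another miRNA profile than untreated cells, and the effects below are estimated within each experiment. No array measured the mRNA or protein of EKLF, GATA1 or NFE2, so the extent of overexpression and knockdown is unknown.

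**Figure D1:**
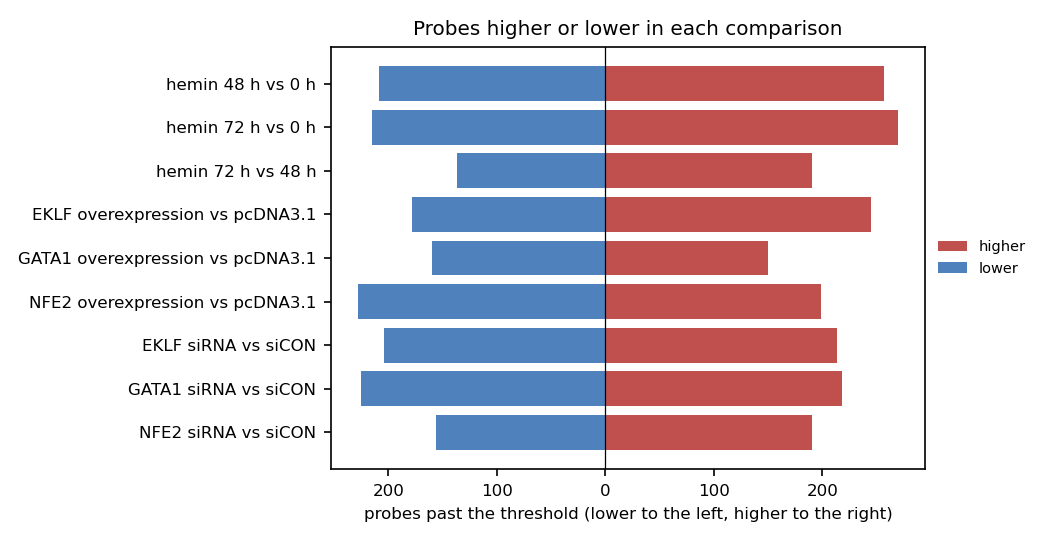
Horizontal bars give the number of the 867 tested probes past the threshold in each comparison, higher to the right and lower to the left of 0. The counts run from 310 for GATA1 overexpression to 485 for 72 h of hemin.

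The first question was which miRNAs change when K562 cells are treated with hemin, which starts haemoglobin synthesis in this line. After 48 h, miR-451, an erythroid miRNA that accumulates in red cell maturation, rose by 3.45 ± 0.15 (adjusted p = 4.04e-11). miR-23a rose by 1.99 ± 0.11 and miR-27a by 1.62 ± 0.07, whereas miR-24 of the same cluster fell by 0.50 ± 0.12. miR-221 rose by 1.89 ± 0.16 and its neighbour miR-222, which with it represses KIT, fell by 1.23 ± 0.10. miR-223 rose by 0.23 ± 0.09 (adjusted p = 0.0476), but with cyclic loess it was at −0.29. This call was lost with any one of 3 arrays left out, at a log2 change of 0.09 without 0 h array 2, 0.19 without 48 h array 1 and 0.27 without 48 h array 2. It was also lost for miR-223 without background correction (0.17), with median scaling (0.02), in the authors' table (0.09), with the experiment normalized alone (0.12), without the 3 dimmest groups (0.18) and without a filter (adjusted p = 0.0563). No change was called for miR-144 (−0.20 ± 0.18), miR-486-5p (−0.09 ± 0.16), miR-155 (below background at 48 h) and the hypoxia-induced miR-210 (0.04 ± 0.06, but −0.41 with median scaling, −0.90 with cyclic loess and −0.34 in the authors' table).

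The 10 largest rises at 48 h were those of miR-193b, 624*, 26b*, 154, 425, 148a, 20a*, 302d, 589 and 128. miR-193b rose at least 32.3-fold, miR-26b* at least 25.2-fold, miR-154 at least 20.4-fold and miR-589 at least 14.6-fold from below background. The other 6 rose by 3.93 to 4.90, with miR-425 at 4.42 ± 0.10 and miR-302d, of a family known from pluripotent cells, at 4.23 ± 0.09. Among the 10 largest falls, miR-1183 fell at least 73.7-fold, miR-944 at least 49.8-fold, miR-876-3p at least 33.9-fold, the shared probe of miR-520c-3p and miR-520f at least 32.1-fold, miR-1290 at least 30.4-fold and miR-623 at least 24.8-fold, to below background. miR-1304 (−5.68 ± 0.06), miR-1285 (−5.12 ± 0.07), miR-299-3p (−5.11 ± 0.16) and miR-551a (−5.00 ± 0.07) fell and stayed detected.

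By list at 48 h, the chromosome 19 cluster, a primate cluster expressed mainly in placenta, had 15 of 28 members lower, 2 higher and 11 not past the threshold. The shared probe of miR-520c-3p and miR-520f, miR-520e (at least 21.0-fold) and miR-518f (at least 5.79-fold) fell to below background. The list median was −0.45, also with bounded members at their bound, and its mean −0.89 (camera Down, adjusted p = 0.0305; adjusted p = 0.244 with an estimated correlation, and 0.0949 without a filter). Of 15 miRNAs reported to rise in erythroid maturation, 6 rose, among them miR-15b (3.68 ± 0.07), 4 fell and 5 did not pass. Of 11 reported to fall, 6 rose, among them miR-103 (2.88 ± 0.09), 2 fell and 3 did not pass. The let-7 family, which represses growth genes, had 1 member that rose (let-7g, 1.83 ± 0.11), 4 that fell, such as let-7e (−2.55 ± 0.10) and let-7a (−1.98 ± 0.07), and 3 not passed. For the miR-17-92 cluster and paralogs these counts were 9, 5 and 7, with miR-106b* up by 2.75 ± 0.10. They were 5, 2 and 3 for the miR-23/27/24 clusters, 3, 2 and 1 for the miR-15/16 family, 2, 0 and 4 for miR-181 (miR-181a-2* at 3.41 ± 0.25), 2, 2 and 3 for miR-30 (miR-30b at 1.79 ± 0.14) and 4, 0 and 2 for miR-29 (miR-29b at least 2.55-fold).

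The megakaryocyte and myeloid list had 5 members that rose, 5 that fell, such as miR-34a (at least 9.0-fold), and 4 not passed at 48 h. In that order the counts were 3, 2 and 6 for lymphoid and pan-leukocyte, 2, 2 and 4 for hypoxia and stress, 35, 17 and 9 for the chromosome 14 imprinted cluster (adjusted p = 0.382) and 0, 1 and 3 for the X-linked cluster. Among the markers of other cell types they were 2, 0 and 6 for epithelial, 0, 1 and 5 for striated muscle, 5, 1 and 3 for neural, with miR-132 up by 3.29 ± 0.17, and 2, 0 and 1 for liver, where miR-194 rose at least 6.31-fold and miR-192 at least 3.97-fold. Adjusted over the list alone, all 19 lists had the same counts, and camera gave 18 of them adjusted p-values from 0.382 to 0.978. Median, mean and test differed in sign for the miR-181 list (−0.10, 0.47, Up), miR-30 (−0.01, 0.23, Up), epithelial (−0.02, 0.28, Up), megakaryocyte and myeloid (0.05, −0.03, Up), lymphoid (0.00, −0.06, Down) and hypoxia (0.03, 0.06, Down).

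In all, 466 of 867 probes passed at 48 h, 257 higher and 209 lower, and 237 changed at least 2-fold. Of those that passed, 157 were below background in one group and 292 were detected in both. With cyclic loess the split was 256 higher and 323 lower, and the median of all probes was −0.09, against 0.14 with median scaling and −0.03 in the fit reported here.

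After 72 h of hemin, miR-451 was higher by 3.93 ± 0.15 (adjusted p = 8.96e-12), miR-23a by 2.37 ± 0.11 (not called with cyclic loess, 0.30) and miR-27a by 1.27 ± 0.07 (but at −0.30 with cyclic loess). miR-221 fell by 2.76 ± 0.16 and miR-222 by 1.71 ± 0.10. miR-210 rose by 0.77 ± 0.06, but was not called with median scaling (0.09) and fell by 0.37 with cyclic loess. miR-223 rose by 0.30 ± 0.09 (adjusted p = 0.0104), but was at −0.30 with median scaling and −0.81 with cyclic loess, and lost its call without 0 h array 2 (0.16) or 72 h array 2 (0.22), with the experiment normalized alone (0.16) and in the authors' table (0.11). Not past the threshold were miR-144 (−0.27 ± 0.18), miR-155 (−0.12 ± 0.15), miR-486-5p (0.17 ± 0.16, but −0.64 with median scaling, −0.53 with cyclic loess and −0.23 in the authors' table) and miR-24 (0.06 ± 0.12, but −1.18 with cyclic loess). miR-21, a growth-associated miRNA and the brightest probe at 72 h (14.07), rose by 1.69 ± 0.12, with no call under median scaling (0.13).

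The largest rises at 72 h were those of miR-624* (5.99 ± 0.09), miR-425 (5.11 ± 0.10), miR-148a (4.90 ± 0.13), miR-20a* (4.57 ± 0.10), miR-128 (4.33 ± 0.14) and miR-1274b (4.0 ± 0.06), and from below background those of miR-193b (at least 45.1-fold), miR-154 (25.9-fold), miR-26b* (17.2-fold) and miR-424 (14.8-fold). The largest falls to below background were those of miR-1183 (at least 78.9-fold), miR-944 (53.3-fold), miR-520c-3p and miR-520f (34.4-fold), miR-219-5p (30.2-fold) and miR-623 (26.5-fold). miR-1304 (−5.64 ± 0.06), miR-1285 (−5.25 ± 0.07), miR-299-3p (−5.23 ± 0.16) and miR-551a (−4.97 ± 0.07) also fell, as did miR-876-3p (−5.19 ± 0.18), which was detected on 1 of the 2 arrays at 72 h.

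The chromosome 14 imprinted cluster, transcribed from the maternal DLK1-DIO3 region, had 39 of 61 members higher at 72 h, 14 lower and 8 not passed. miR-154, miR-409-5p (at least 10.3-fold) and miR-889 (3.16 ± 0.17) rose and miR-299-3p fell. Its median was 0.73 (0.70 with bounded members at their bound) and its mean 0.56 (camera Up, adjusted p = 0.0305; adjusted p = 0.259 with an estimated correlation). That call was also lost with median scaling (adjusted p = 0.0595), cyclic loess (0.38), the stricter filter (0.245) and the authors' table (0.221). Members of the chromosome 19 cluster numbered 14 of 28 lower, 1 higher and 13 not passed, with miR-520e at −3.13 ± 0.13. Its median was −0.45, also with bounds, and its mean −0.89 (camera Down, adjusted p = 0.0305; adjusted p = 0.244 with an estimated correlation, 0.0583 with cyclic loess and 0.0949 without a filter). Of the miRNAs reported to rise in erythroid maturation, 7 rose, such as miR-15b (3.52 ± 0.07) and miR-22 (at least 4.65-fold), 6 fell, such as miR-486-3p (−2.37 ± 0.08), and 2 did not pass. Of those reported to fall, 6 rose, such as miR-103 (2.66 ± 0.09), 2 fell (miR-221 and miR-222) and 3 did not pass. The let-7 family had 2 up (let-7g at 1.65 ± 0.11), 5 down (let-7e at −2.34 ± 0.10) and 1 not passed; the miR-17-92 list had 11, 5 and 5, with miR-106b* at 3.63 ± 0.10. The liver markers had 2 up (miR-194 at least 6.51-fold, miR-192 at least 4.38-fold) and 1 not passed, and the neural markers 5, 3 and 1 (miR-132 at 3.53 ± 0.17). Adjusted over the list alone, these counts were the same; the other 17 lists had camera adjusted p-values from 0.525 to 0.950.

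In all, 485 probes passed at 72 h, 270 higher and 215 lower, and 260 changed at least 2-fold; 151 of them were below background in one group. With median scaling the split was 248 higher and 477 lower, with the median of all probes at −0.39 against −0.04, and with cyclic loess 247 and 431, with that median at −0.22; with the hemin experiment normalized alone it was 295 and 378.

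**Figure D2:**
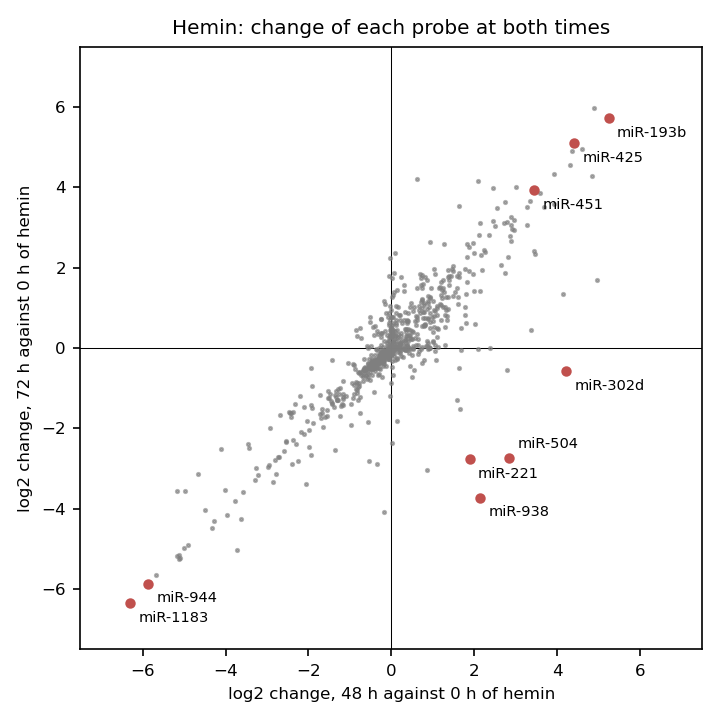
Each point is a probe, with its log2 change after 48 h of hemin on the horizontal axis and after 72 h on the vertical axis, both against 0 h. Most probes lie near the diagonal (r = 0.871 across probes), while miR-221, miR-504 and miR-938 were higher at 48 h and lower at 72 h.

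The comparisons of 48 h and 72 h with 0 h shared the 0 h arrays. Across 867 probes, which are not independent replicates, their effects correlated at r = 0.871, and 198 probes rose at both times (80 if independent) and 181 fell at both (51.8), with 20 opposite. Simulated data without an effect gave r = 0.492 and a covariance of 0.0119 against 1.741 observed. The draws held only the spread between arrays of a group, not a control sample that differs as a whole. Part of the excess may still come from the shared controls, which 2 arrays cannot separate.

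Between 48 h and 72 h, the question was which miRNAs kept changing with time. miR-221 fell by 4.65 ± 0.16, miR-938 by 5.87 ± 0.08, miR-504 by 5.59 ± 0.07 and miR-632 by 3.90 ± 0.06, and miR-302d fell at least 26-fold to below background. miR-1197 (2.25 ± 0.07), miR-424 (2.06 ± 0.06), miR-374a (1.89 ± 0.18) and miR-594:9.1 (1.84 ± 0.13) rose, and miR-1181 rose at least 4.52-fold. miR-451 rose by a further 0.49 ± 0.15 (adjusted p = 0.0182), but was at −0.09 with cyclic loess, was not called with median scaling (0.19) and was lost with any array of the 4 left out (0.47 to 0.51). miR-210 rose by 0.73 ± 0.06, and miR-222 fell by 0.48 ± 0.10. miR-24 rose by 0.55 ± 0.12, but was not called with median scaling (0.22) and was at −0.11 with cyclic loess. miR-23a rose by 0.38 ± 0.11, but was at −0.11 with median scaling and −0.45 with cyclic loess, and was not called in the authors' table (0.23) or without 48 h array 2 (0.34) or 72 h array 1 (0.30). miR-27a fell by 0.34 ± 0.07, with no call in the authors' table (−0.15). Not passed were miR-144 (−0.07), miR-155 (below background at 48 h), miR-223 (0.07, but −0.51 with cyclic loess) and miR-486-5p (0.26, but −0.55 with median scaling, −0.40 with cyclic loess and −0.22 in the authors' table).

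By list, 31 of 61 members of the chromosome 14 cluster rose from 48 h to 72 h, such as miR-494 (1.13 ± 0.15) and miR-376b (1.12 ± 0.17), 7 fell and 23 did not pass (camera adjusted p = 0.0921; 31 and 10 adjusted over the list alone). The list was called Up without background correction (adjusted p = 0.0297), with an offset of 50 (0.0378), with median scaling (0.022) and without a filter (0.0408). Among the miRNAs reported to rise in erythroid maturation, 4 rose, such as miR-144* (1.08 ± 0.05), 2 fell, such as miR-486-3p (−2.40 ± 0.08), and 9 did not pass. The miR-15/16 family had 3 up, such as miR-503 (1.45 ± 0.07), and 3 not passed. The myeloid list had 5 up, such as miR-125b (at least 2.26-fold), 1 down and 8 not passed. Neural markers had 4 up (miR-9* at 1.72 ± 0.08), 2 down (miR-129-5p at −2.14 ± 0.13) and 3 not passed, and epithelial markers 2, 2 and 4 (miR-200c at −0.96 ± 0.12), where the median was 0.02 and the mean −0.12 (test Down). These last 5 lists had the same counts adjusted over the list alone, and the other 18 lists had camera adjusted p-values from 0.554 to 0.967. In all, 328 probes passed, 191 higher and 137 lower, of which 76 changed at least 2-fold. The split was 130 higher and 443 lower with median scaling (median of all probes −0.38 against 0.01) and 188 and 317 with cyclic loess (median −0.11).

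The overexpression arrays addressed which miRNAs change with more EKLF, an activator of beta-globin. miR-22, which has been described in erythroid maturation, rose at least 46.1-fold from below background, miR-27a at least 20.0-fold and miR-24 at least 1.36-fold; miR-23a rose by 1.18 ± 0.11, with no call under median scaling (0.25). miR-451 fell by 2.01 ± 0.15 (adjusted p = 2.54e-08) and miR-221 by 3.47 ± 0.16, while miR-222 rose by 5.76 ± 0.10, detected on 1 of the 2 control arrays. miR-223 rose by 3.33 ± 0.09, with raw signals of 111 and 143 against 103 and 116. miR-144 rose by 1.05 ± 0.18 and miR-155 by 0.68 ± 0.15, the latter with no call under cyclic loess (0.01). miR-486-5p fell by 0.66 ± 0.16, but was at 0.80 with cyclic loess. miR-210 was below background in both groups.

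The 10 largest rises on EKLF overexpression were those of miR-1268 (at least 152-fold), miR-885-5p (135-fold), miR-542-5p (117-fold), miR-449a (103-fold), miR-562 (95.5-fold), miR-645 (68.1-fold) and miR-337:9.1 (66.7-fold) from below background, and of miR-431 (6.99 ± 0.15), miR-376c (6.65 ± 0.15) and miR-31 (7.58 ± 0.21, detected on 1 control array). The largest falls to below background were those of miR-219-5p (at least 99.2-fold), miR-302a* (91.4-fold), miR-129-3p (75.3-fold), miR-199a-3p and miR-199b-3p (74.0-fold), miR-1274a (71.5-fold) and miR-454* (53.6-fold). miR-654-3p (−6.67 ± 0.14), miR-15a* (−6.45 ± 0.10) and miR-302d (−6.37 ± 0.09) also fell, as did miR-1197 (−6.37 ± 0.07, detected on 1 EKLF array).

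Of the 15 miRNAs reported to rise in erythroid maturation, 2 rose (miR-22 and miR-144), 5 fell, such as miR-15b (at least 9.64-fold), and 8 did not pass with EKLF overexpression. Of the 11 reported to fall, 5 rose, such as miR-191 (at least 7.95-fold), 3 fell and 3 did not pass. The miR-17-92 list had 10 up, 4 down, among them miR-18a (at least 47.1-fold) and miR-106b (at least 28.3-fold), and 7 not passed, with a positive median (0.25) and test and a negative mean (−0.47). The lymphoid and pan-leukocyte list had 1 up, 5 down, such as the haematopoietic miR-142-3p (at least 42.7-fold) and miR-26b (at least 28.0-fold), and 5 not passed. The megakaryocyte and myeloid list had 5 up, such as miR-146b-5p (4.37 ± 0.07, detected on 1 control array), 2 down and 7 not passed. In the chromosome 19 cluster there were 10, 4 and 14, with miR-520e up by 6.5 ± 0.13 (detected on 1 control array) and miR-518b down at least 46.5-fold, and the chromosome 14 cluster 16, 10 and 35 (15 and 9 adjusted over the list alone), with miR-299-5p up at least 80.6-fold. Among markers of other cell types, neural had 1 up (miR-132, 3.26 ± 0.17), 6 down, such as miR-9* (at least 39.5-fold), and 2 not passed, epithelial 1, 3 and 4, with the keratinocyte miR-203 down at least 46.7-fold, and liver 2, 1 and 0, with miR-192 up by 2.83 ± 0.09. For the other lists named here, adjustment over the list alone left the counts the same, and no list passed camera (adjusted p from 0.324 to 0.953), though with cyclic loess the chromosome 14 cluster was called Up (adjusted p = 0.0238).

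With EKLF overexpression, 423 probes passed, 245 higher and 178 lower, 244 of them at least 2-fold; 130 were below background in one group. The split was 514 higher and 173 lower with median scaling, with the median of all probes at 0.42 against 0.04, and 311 and 133 in the authors' table, where EKLF overexpression had 1 array, as the column of the other is a copy and was left out. Mean signal was 135.6 on these arrays against 441.7 on the controls, and quantile normalization gave both the same distribution. The bounds given for EKLF overexpression are therefore no bounds on the raw change.

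For GATA1, the master regulator of the erythroid lineage, overexpression left miR-451 without a call (0.01 ± 0.15, but −0.65 in the authors' table, with 1 GATA1 array), as it did miR-144 (0.37 ± 0.18), miR-221 (0.25 ± 0.16), miR-155 (−0.22 ± 0.15) and miR-222 (−0.13 ± 0.10, detected on 1 array of each group, but 0.36 with median scaling). miR-223 rose by 3.44 ± 0.09 and miR-23a by 2.39 ± 0.11, and miR-24 rose at least 5.0-fold from below background. miR-486-5p fell by 2.02 ± 0.16 (adjusted p = 4.91e-08). miR-27a and miR-210 were below background in both groups.

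The largest rises on GATA1 overexpression were those of miR-337:9.1 (at least 65.6-fold), miR-623 (56.6-fold), miR-217 (51.6-fold), miR-15b* (45.3-fold), miR-376a*:9.1 (41.6-fold), miR-517a and miR-517b (37.3-fold) and miR-944 (35.6-fold) from below background, and of miR-99b* (5.65 ± 0.14), miR-584 (6.66 ± 0.10) and miR-154 (6.15 ± 0.06), the last pair detected on 1 control array. Falls to below background were led by miR-219-5p (at least 103-fold), miR-302a* (95.2-fold), miR-129-3p (78.5-fold), miR-18a (49.1-fold), miR-203 (48.7-fold), miR-142-3p (44.5-fold), miR-1273 (37.9-fold) and miR-1308 (35.7-fold). miR-371-5p fell by 5.86 ± 0.13 and miR-202*:9.1 by 5.88 ± 0.09, the latter detected on 1 GATA1 array.

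Of the miRNAs reported to rise in erythroid maturation, 1 rose, 4 fell, such as miR-16 (−4.30 ± 0.11, detected on 1 GATA1 array) and miR-15b (at least 10-fold), and 10 did not pass with GATA1 overexpression. Of those reported to fall, 3 rose, such as miR-107 (at least 3.58-fold), 2 fell and 6 did not pass. The miR-17-92 list had 3 up, 7 down, such as miR-106b (at least 29.5-fold) and miR-93 (−4.24 ± 0.12, detected on 1 GATA1 array), and 11 not passed. The myeloid list had 3 up, such as miR-146a (at least 9.63-fold), 2 down and 9 not passed (4 up and 2 down adjusted over the list alone). The chromosome 19 cluster had 6, 7 and 15, with miR-512-3p up by 3.99 ± 0.08, and the chromosome 14 cluster 9, 8 and 44, with miR-487a up at least 19.9-fold; for both, median and mean differed in sign (−0.04 and 0.24, −0.02 and 0.24), with the test Up. Epithelial markers had 4 up, miR-200c (3.85 ± 0.12), miR-200a (at least 8.50-fold) and miR-141 (at least 6.94-fold) among them, and 4 down, among them miR-203. Liver markers had 1 down (miR-192, at least 12.5-fold) and 2 not passed. The other lists named here kept their counts adjusted over the list alone, and no list passed camera (adjusted p from 0.525 to 0.978).

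With GATA1 overexpression, 310 probes passed, 150 higher and 160 lower, 187 of them at least 2-fold; 119 were below background in one group. The split was 555 higher and 120 lower with median scaling (median of all probes 0.49 against −0.01), and 247 and 172 with cyclic loess (0.07).

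NFE2, a partner of small Maf proteins at globin enhancers, gave on overexpression a rise of miR-451 by 1.68 ± 0.15 (adjusted p = 1.68e-07) and of miR-486-5p by 1.42 ± 0.16, and miR-486-3p of the same precursor rose at least 24.6-fold from below background. miR-223 fell by 1.81 ± 0.09. miR-23a fell by 0.28 ± 0.11 (adjusted p = 0.0494), but was at 0.21 with median scaling, and was not called without either NFE2 array (−0.26 and −0.30) or pcDNA3.1 array 2 (−0.16), with an offset of 50 (−0.20), with the experiment normalized alone (−0.16), without a filter (adjusted p = 0.0598), with trend and robust options (adjusted p = 0.0514) or among probes detected in both groups (adjusted p = 0.051). miR-222, detected on 1 control array, fell at least 1.12-fold to below background, a call lost with median scaling (−0.33), an offset of 50 (−0.14) and without either NFE2 array (−0.27 and −0.32) or pcDNA3.1 array 2 (−0.24). Not passed were miR-221 (−0.11 ± 0.16), miR-144 (−0.35 ± 0.18), miR-155 (−0.32 ± 0.15) and miR-24, and miR-27a and miR-210 were below background in both groups.

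The largest rises on NFE2 overexpression were those of miR-432 (at least 87.0-fold), miR-1179 (60.3-fold), miR-1304 (57.3-fold), miR-612 (47.0-fold), miR-16-1* (45.1-fold), miR-1182 (42.9-fold) and miR-220a (40.1-fold) from below background, and of miR-631 (6.07 ± 0.19), miR-380 (5.96 ± 0.18) and miR-146b-5p (6.31 ± 0.07, detected on 1 control array). Falls to below background included those of miR-219-5p (at least 119-fold), miR-302a* (109.7-fold), miR-1197 (98.1-fold), miR-454* (64.3-fold), miR-203 (56.1-fold), let-7g* (37.9-fold) and miR-106b (34.0-fold). miR-371-5p fell by 5.90 ± 0.13, and miR-1274a (−6.45 ± 0.09) and miR-331-5p (−6.29 ± 0.10) fell with detection on 1 NFE2 array.

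Erythroid maturation miRNAs reported to rise split into 5 that rose, miR-451, miR-486-5p and miR-486-3p among them, 3 that fell and 7 not passed with NFE2 overexpression. Of those reported to fall, 2 rose, 3 fell, such as miR-126 (−2.90 ± 0.14), a miRNA of endothelium and megakaryocytes, and 6 did not pass. The miR-17-92 list had 7 up, 9 down, such as miR-20a* (at least 13.0-fold), and 5 not passed. The let-7 family had 1 up (let-7b, at least 5.58-fold), 1 down and 6 not passed, and the lymphoid list 1, 4 and 6, with miR-26b down by 4.22 ± 0.10. The chromosome 19 cluster had 4 up, such as miR-520e (5.58 ± 0.13, detected on 1 control array), 16 down, such as miR-512-5p (at least 28.3-fold), and 8 not passed, and the chromosome 14 cluster 8, 12 and 41 (8 and 9 adjusted over the list alone), with miR-134 up at least 29.4-fold and a median of −0.05, a mean of 0.19 and the test Up. The hypoxia and stress list had 3 up, such as the p53 target miR-34b (at least 12.7-fold), 3 down and 2 not passed (median 0.00, mean 0.39, test Up). Among markers of other cell types, neural had 1 up, 5 down (miR-9* at −3.17 ± 0.08) and 3 not passed, liver 1, 2 and 0 (miR-192 at −3.10 ± 0.09) and epithelial 2, 3 and 3. In the other lists named here, the counts adjusted over the list alone were the same, and no list passed camera (adjusted p from 0.659 to 0.978).

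With NFE2 overexpression, 427 probes passed, 199 higher and 228 lower, 236 of them at least 2-fold; 150 were below background in one group. With median scaling 199 were higher and 107 lower, with the median of all probes at −0.17 against −0.06.

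The 3 overexpression comparisons shared the pcDNA3.1 arrays, and miR-219-5p, an oligodendrocyte miRNA, and miR-302a* were the largest falls in each. For EKLF and GATA1, 97 probes fell in both (32.8 if independent), 46 rose in both (42.4) and 71 went opposite ways (r = 0.367 across probes, covariance 1.286). For EKLF and NFE2 the counts were 112 (46.8), 52 (56.2) and 112 (r = 0.367, covariance 1.333), and for GATA1 and NFE2 they were 110 (42.1), 39 (34.4) and 68 (r = 0.368, covariance 1.166). Simulated data without an effect gave r of 0.496, 0.499 and 0.498 with covariances of 0.0120, 0.0121 and 0.0121. These draws held only the spread between arrays of a group, not a control sample that differs as a whole. Part of the shared falls may still come from the shared controls, which 2 arrays cannot separate.

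The siRNA arrays addressed which miRNAs change with less EKLF. miR-221 rose by 3.42 ± 0.16 and miR-222 by 5.83 ± 0.10, the latter detected on 1 control array. miR-27a fell at least 16.8-fold to below background and miR-23a by 5.31 ± 0.11, detected on 1 EKLF siRNA array. miR-451, detected on 1 EKLF siRNA array, was at −0.38 ± 0.15 (adjusted p = 0.0505), not past the threshold. miR-223 fell by 1.19 ± 0.09, but was at 0.04 with median scaling. miR-24 fell by 0.43 ± 0.12, but was at 1.5 with median scaling, 0.58 with cyclic loess and 0.70 in the authors' table, and lost its call without EKLF siRNA array 2 (−0.35). miR-144 fell by 0.55 ± 0.18, but was at 0.01 with cyclic loess and was not called without siCON array 1 or either EKLF siRNA array (−0.44 to −0.61), without background correction (−0.36), with an offset of 50 (−0.32), with the experiment normalized alone (−0.33) or in the authors' table (0.00). miR-486-5p fell by 0.48 ± 0.16, but was at 0.02 with median scaling and was not called without any 1 of the 4 arrays (−0.43 to −0.48). miR-155 was at −0.08 ± 0.15 and miR-210 below background in both groups.

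The largest rises with EKLF siRNA were those of miR-504 (at least 176-fold), miR-1268 (143-fold), miR-202*:9.1 (109-fold), miR-378* (83.6-fold), miR-1248 (78.6-fold), miR-449a (68.3-fold), miR-622 (67.6-fold) and miR-1181 (59.4-fold) from below background, and of miR-302b* (6.75 ± 0.19) and miR-302d (6.41 ± 0.09), both detected on 1 control array. The largest falls to below background were those of miR-432 (at least 149.9-fold), miR-182 (126-fold), miR-486-3p (91.7-fold), miR-224 (82.3-fold), miR-16-2* (73.6-fold), let-7a (72.2-fold), miR-1179 (67.1-fold) and miR-421 (44.7-fold), and miR-768-3p of an older miRBase release (−6.24 ± 0.13) and miR-539 (−5.93 ± 0.23) fell too.

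Of the 15 miRNAs reported to rise in erythroid maturation, 10 fell with EKLF siRNA, 1 rose and 4 did not pass (11 fell and 1 rose adjusted over the list alone). Besides miR-182 and miR-486-3p, miR-183 of the miR-182 cluster fell at least 35.7-fold and miR-22 by 3.79 ± 0.06. The list median was −1.06, also with bounded members at their bound, and its mean −2.05 (camera Down, adjusted p = 0.0305; adjusted p = 0.285 with an estimated correlation). The call was also lost with median scaling (adjusted p = 0.504) and the stricter filter (0.0655). Of the miRNAs reported to fall, 3 rose, 6 fell, such as miR-103 (at least 33.0-fold) and miR-107 (at least 6.96-fold), and 2 did not pass. The miR-15/16 family had 4 down and 2 not passed, with miR-15b at −1.42 ± 0.07 and miR-16 at −1.06 ± 0.11, but miR-16 was at 1.12 with median scaling and 0.25 in the authors' table. The miR-23/27/24 clusters had 2 up (miR-24-2* at 4.25 ± 0.09), 5 down and 3 not passed, the miR-17-92 list 5, 10 (miR-17* at least 13.7-fold) and 6 (6 up adjusted over the list alone), and the miR-30 family 3 (miR-30c at 5.70 ± 0.15), 1 and 3. The myeloid list had 5 down, such as miR-99b (at least 13.5-fold), and 9 not passed, and the lymphoid list 1 up, 4 down (miR-342-3p at least 6.82-fold) and 6 not passed. For the chromosome 19 cluster these were 8, 7 and 13, with miR-520g down at least 20.4-fold (median 0.08, mean −0.24, test Down), and the chromosome 14 cluster 13, 23 and 25 (24 down adjusted over the list alone), with miR-431 down at least 55.9-fold. Striated muscle markers had 4 up, such as the cardiac miR-208a (at least 42.6-fold), and 2 not passed. Adjusted over the list alone, the counts of the other lists named here were the same, and the other 18 lists had camera adjusted p-values from 0.525 to 0.971.

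With EKLF siRNA, 418 probes passed, 214 higher and 204 lower, 254 of them at least 2-fold; 161 were below background in one group. With median scaling 153 were higher and 642 lower, and the median of all probes was −0.96 against 0.00. Mean signal was 102.6 on the siCON arrays against 414.1 on the EKLF siRNA arrays, and miR-451 had raw signals of 34.0 and 31.0 in siCON. With so dim a control, the bounds given for the siRNA comparisons are no bounds on the raw change.

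With GATA1 siRNA, miR-451 rose by 1.83 ± 0.15 (adjusted p = 6.72e-08), whereas miR-144, transcribed with it, fell by 0.75 ± 0.18, with no call under cyclic loess (−0.08) or in the authors' table (0.00). In siCON, miR-451 was detected but dim, at 5.12 and level with miR-155 (5.12). Mean signal was 102.6 on the siCON arrays against 515.7 with GATA1 siRNA, so the rise of miR-451 started near the floor of a dim control. miR-27a fell by 2.48 ± 0.07 and miR-223 by 1.63 ± 0.09, and miR-222 rose by 2.07 ± 0.10, detected on 1 control array. miR-24 fell by 1.34 ± 0.12, but was at 0.79 with median scaling and 0.52 in the authors' table, and was not called with cyclic loess (−0.44). miR-23a fell by 0.38 ± 0.11, but was at 1.60 with median scaling, 0.13 with cyclic loess and 1.29 in the authors' table, and was not called without siCON array 1 (−0.30) or GATA1 siRNA array 1 (−0.31). miR-221 fell by 0.43 ± 0.16, but was at 1.44 with median scaling and 1.27 in the authors' table, and was not called without siCON array 1 (−0.20) or either GATA1 siRNA array (−0.40 and −0.46) or with the experiment normalized alone (−0.51, adjusted p = 0.0714). miR-486-5p (−0.22 ± 0.16) and miR-155 (0.13 ± 0.15, but −1.04 with median scaling) did not pass, and miR-210 was below background in both groups.

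The largest rises with GATA1 siRNA were those of miR-202*:9.1 (at least 103-fold), miR-646 (62.1-fold), miR-504 (56.1-fold), miR-1181 (37.7-fold) and miR-378* (25.7-fold) from below background, of miR-92b (6.07 ± 0.15) and miR-376b (5.45 ± 0.17), and of miR-1281 (7.41 ± 0.29), miR-549 (6.99 ± 0.34) and miR-374a (5.51 ± 0.18), detected on 1 control array. Falls to below background were led by miR-16-2* (at least 80.1-fold), miR-329 (57.3-fold), miR-148a (55.4-fold), miR-421 (48.7-fold), miR-574-3p (38.2-fold), miR-944 (28.1-fold) and miR-502-3p with miR-500* (27.6-fold). miR-1179 (−5.51 ± 0.06) and miR-1233 (−5.28 ± 0.45) fell, as did miR-431 (−6.01 ± 0.15, detected on 1 GATA1 siRNA array).

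Of the miRNAs reported to rise in erythroid maturation, 2 rose, 6 fell, such as miR-22 (at least 20.6-fold), and 7 did not pass with GATA1 siRNA. Of those reported to fall, 2 rose, 6 fell, among them miR-107 (at least 7.58-fold) and miR-103 (−1.47 ± 0.09, but 0.77 with median scaling, 0.73 with cyclic loess and 0.46 in the authors' table), and 3 did not pass. The miR-23/27/24 clusters had 2 up (miR-27a* at 2.80 ± 0.27), 7 down (miR-23a* at −3.50 ± 0.22) and 1 not passed. The miR-17-92 list had 5 up, such as miR-106b* (at least 10.2-fold), 10 down and 6 not passed, with a negative median (−0.30) and test and a positive mean (0.23); with median scaling it was called Up (adjusted p = 0.0158). The let-7 family had 3 up (let-7g at least 5.87-fold), 2 down and 3 not passed, and the miR-30 family 3 up (miR-30c at 4.04 ± 0.15), 2 down and 2 not passed. The chromosome 19 cluster had 8, 8 and 12, with miR-520g down at least 22.2-fold (median 0.01, mean −0.44, test Down), the chromosome 14 cluster 13, 20 and 28, and the X-linked cluster 1 (miR-513b at least 3.75-fold), 1 and 2. Liver markers had 2 up (miR-194 at least 15.9-fold, miR-192 at least 11.8-fold) and 1 not passed, and neural markers 4 up (miR-128 at least 20.2-fold), 2 down and 3 not passed. Adjusted over the list alone, the counts of these lists were the same, and no list passed camera (adjusted p from 0.487 to 0.972).

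With GATA1 siRNA, 443 probes passed, 218 higher and 225 lower, 230 of them at least 2-fold; 168 were below background in one group. The split was 166 higher and 661 lower with median scaling (median of all probes −1.57 against −0.01), 238 and 374 with cyclic loess (−0.11) and 181 and 108 in the authors' table.

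With NFE2 siRNA, miR-24 fell at least 21.6-fold to below background and miR-223 fell by 2.97 ± 0.09 (adjusted p = 5.41e-13), while miR-222 rose by 5.95 ± 0.10, detected on 1 control array. miR-27a rose by 0.31 ± 0.07. miR-23a fell by 0.66 ± 0.11, but was at 0.31 with median scaling and was not called with cyclic loess (−0.08) or in the authors' table (−0.08). miR-144 rose by 0.74 ± 0.18, but was not called with median scaling (0.02), cyclic loess (0.21), the authors' table (0.15) or without NFE2 siRNA array 2 (0.54). Not passed were miR-451 (−0.12 ± 0.15), miR-221 (−0.39 ± 0.16), miR-155 (0.00 ± 0.15) and miR-486-5p (0.06 ± 0.16, but −1.0 with cyclic loess and −0.29 in the authors' table), and miR-210 was below background in both groups.

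The largest rises with NFE2 siRNA, from below background except for miR-222, were those of miR-488* (at least 80.5-fold), miR-192 (76.5-fold), miR-202*:9.1 (72.8-fold), miR-874 (61.1-fold), miR-498 (60.1-fold), miR-146a (55.2-fold), miR-885-5p (42.3-fold), miR-23b (38.8-fold) and miR-504 (37.3-fold). Falls to below background were led by miR-16-2* (at least 61.6-fold), miR-1179 (56.2-fold), miR-329 (44.1-fold), miR-148a (42.6-fold), miR-425 (39.5-fold), miR-421 (37.4-fold), miR-1260 (36.0-fold), miR-19a (30.4-fold) and miR-574-3p (29.4-fold), and miR-431 fell by 5.89 ± 0.15, detected on 1 NFE2 siRNA array.

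Of the miRNAs reported to rise in erythroid maturation, 2 rose, 6 fell, such as miR-22 (at least 15.8-fold), and 7 did not pass with NFE2 siRNA. Of those reported to fall, 4 rose, 4 fell, such as miR-103 (at least 27.6-fold), and 3 did not pass (5 down adjusted over the list alone). The miR-23/27/24 clusters had 4 up (miR-24-2* at 3.28 ± 0.09), 4 down and 2 not passed (5 down adjusted over the list alone), with a negative median (−0.17) and a positive mean (0.31) and test. The miR-30 family had 3 up (miR-30b at least 22.9-fold), 2 down (miR-30d at −5.11 ± 0.08) and 2 not passed (median 0.30, mean −0.004, test Up), and the lymphoid list 3 up (miR-142-3p at least 9.55-fold, miR-181b at 3.93 ± 0.10 with detection on 1 control array), 3 down and 5 not passed. The chromosome 19 cluster had 4, 6 and 18, with miR-520g down at least 17.0-fold (median 0.04, mean −0.29, test Down), and the chromosome 14 cluster 9, 22 and 30, with miR-379 down by 5.35 ± 0.07 (camera adjusted p = 0.213). Liver markers had 2 up (miR-192 and miR-885-5p) and 1 not passed (camera adjusted p = 0.0955, but called Up with median scaling at 0.0158), and neural markers 2 up (miR-128 at least 8.08-fold), 2 down and 5 not passed. Adjusted over the list alone, the counts of the other lists named here were the same, and the other 17 lists had camera adjusted p-values from 0.525 to 0.978.

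With NFE2 siRNA, 347 probes passed, 191 higher and 156 lower, 178 of them at least 2-fold; 128 were below background in one group. With cyclic loess 86 were higher and 135 lower, and in the values deposited by the authors 95 and 129; the median of all probes was −0.20 with median scaling, where 100 were higher and 110 lower.

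**Figure D3:**
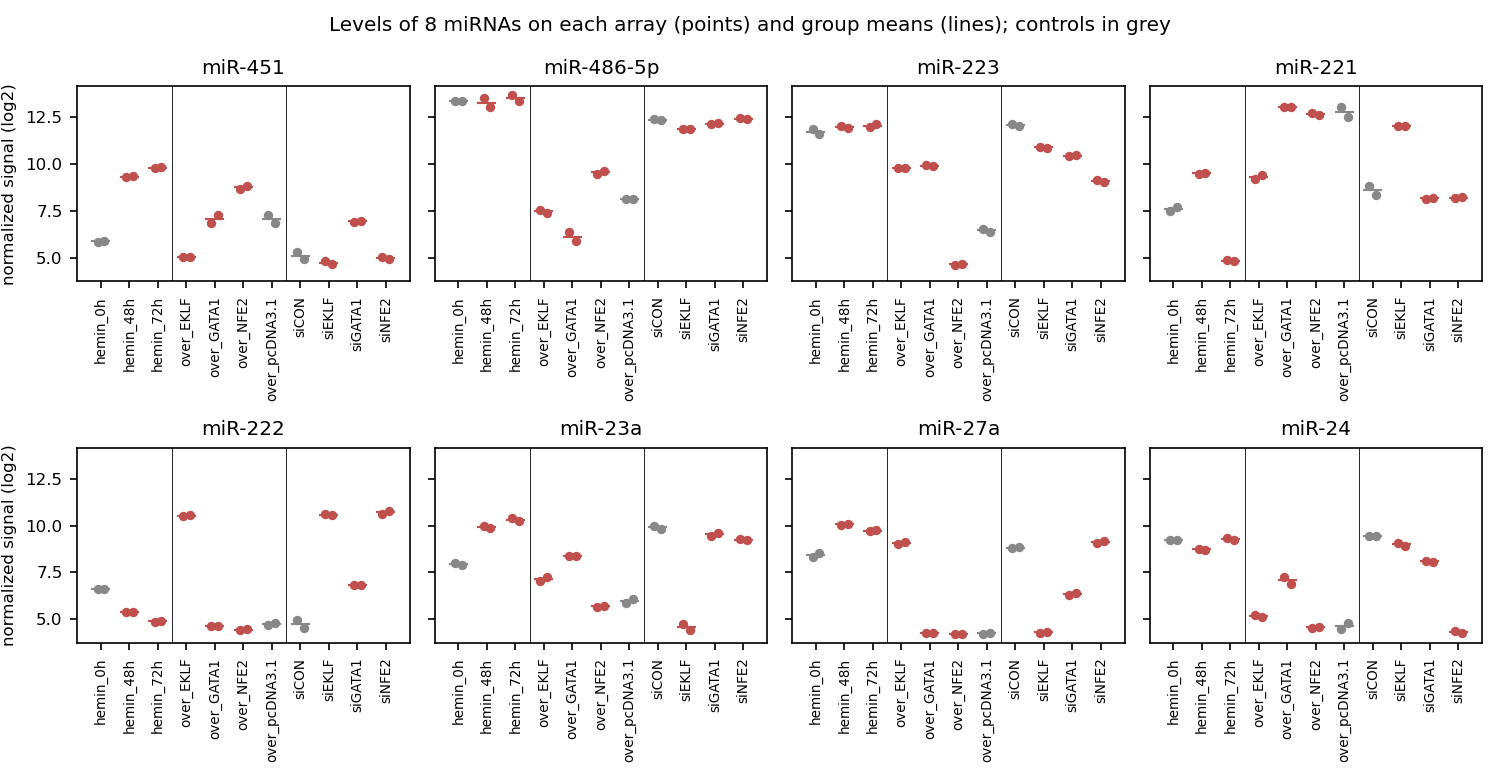
Points give the normalized log2 signal of 8 panel miRNAs on each array and short lines the group means, with control groups in grey and vertical lines between the experiments. miR-451 rises from 5.88 at 0 h to 9.81 at 72 h of hemin, and miR-486-5p lies at 13.34 in untreated and at 8.14 in pcDNA3.1 cells.

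The 3 siRNA comparisons shared the siCON arrays. miR-504, miR-202*:9.1 and miR-222 rose, and miR-16-2*, miR-1179, miR-421 and miR-22 fell, in each. For EKLF and GATA1, 124 probes rose in both (53.8 if independent), 162 fell in both (52.9) and 47 went opposite ways (r = 0.486 across probes, covariance 1.730). For EKLF and NFE2 the counts were 84 (47.1), 114 (36.7) and 64 (r = 0.430, covariance 1.559), and for GATA1 and NFE2 they were 91 (48.0), 119 (40.5) and 53 (r = 0.546, covariance 1.634). Simulated data without an effect gave r of 0.501, 0.501 and 0.492 with covariances of 0.0122, 0.0122 and 0.0119. These draws held only the spread between arrays of a group, not a control sample that differs as a whole. Part of the shared calls may still come from the shared controls, which 2 arrays cannot separate.

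Overexpression and siRNA of the same factor were compared directly, since a miRNA under its control could move in opposite directions. Pairs of unlike factors ranged from 136 opposite and 108 in the same direction for EKLF overexpression and GATA1 siRNA to 93 and 113 for EKLF overexpression and NFE2 siRNA, and their difference from the pairs of the same factor was not tested. For EKLF, 130 probes were called in opposite directions, 69 of them up on overexpression and down with siRNA, and 102 in the same direction. The largest differences in that direction were those of miR-431 (12.86 ± 0.21), miR-520e (10.17 ± 0.18), miR-22, miR-27a (9.31 ± 0.09) and miR-539 (8.33 ± 0.32), and in the other direction those of miR-202*:9.1 (−13.12 ± 0.12), miR-302d (−12.78 ± 0.13), miR-1197 (−12.53 ± 0.10), the probe of miR-199a-3p and miR-199b-3p (−11.26 ± 0.07) and miR-33a (−11.26 ± 0.29). For GATA1, 105 were called in opposite directions, 48 of them up on overexpression, and 86 in the same. miR-944 (10.85 ± 0.11), miR-517a with miR-517b (10.39 ± 0.12), miR-431 (9.73 ± 0.21), miR-663b (6.82 ± 0.18) and miR-1233 (6.76 ± 0.64) had the largest positive differences. miR-202*:9.1 (−13.06 ± 0.12), miR-378*, miR-192 (−8.21 ± 0.13), miR-18a (−7.63 ± 0.09) and miR-219-5p (−7.31 ± 0.09) had the largest negative ones, the last with no siRNA effect called. For NFE2, 113 were called in opposite directions, 44 of them up on overexpression, and 86 in the same. miR-1179 (13.02 ± 0.09), miR-380 (11.12 ± 0.25), miR-1182 (10.22 ± 0.08), miR-517a with miR-517b (10.07 ± 0.12) and miR-520e led on the positive side, and miR-1197 (−12.25 ± 0.10), miR-192 (−9.97 ± 0.13), miR-641 (−8.56 ± 0.19), miR-302a* (−7.64 ± 0.19) and miR-219-5p (−7.18 ± 0.09, with no siRNA effect called) on the negative side. Many of these are below background in at least 1 group, so the fitted sizes depend on the offset and are no bounds. Many also moved the same way in all 3 comparisons with a shared control. With each siRNA miR-431, miR-22, miR-520e, miR-944 and miR-1179 fell, and miR-202*:9.1, miR-302d and miR-378* rose. On each overexpression miR-219-5p, miR-302a* and miR-18a fell. For such probes, signal of the shared control arrays cannot be told apart from an effect of the factor. Others, such as miR-27a and miR-192, did not move alike in this way.

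The tests of the differences passed for 522 probes with EKLF (276 positive, 246 negative), 508 with GATA1 (241 and 267) and 544 with NFE2 (244 and 300). With median scaling the splits were 573 and 210, 619 and 185, and 239 and 147, with medians of all probes of 1.22, 1.86 and 0.02; with cyclic loess the NFE2 split was 243 and 181 (−0.06), and in the authors' table the EKLF split was 339 and 197. Across the 867 probes, which are not independent replicates, the overexpression and siRNA effects of a factor correlated at r = −0.104 for EKLF, −0.063 for GATA1 and −0.090 for NFE2. With median scaling these were −0.263, −0.151 and −0.067, and in the authors' table, with only 1 array of its own for each overexpressed factor, −0.151 for EKLF and −0.095 for GATA1. The 6 pairs of unlike factors gave −0.099 to −0.018. Probes called in both numbered 232 for EKLF (203.9 if independent), 191 for GATA1 (158.4) and 199 for NFE2 (170.9).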

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

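For the patterns below, the tests of separate chance on each array and of low total signal in the pcDNA3.1 arrays were chosen after the result was seen, as was the count of pairs outside the large chromosome 14 cluster.

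The effects of hemin at 48 h and at 72 h differed for 328 probes by a direct test of the difference. The largest positive differences (72 h minus 48 h, log2) among probes detected at both times were those of miR-1197 (2.25), miR-424 (2.06), miR-374a (1.89) and miR-594:9.1 (1.84), and the largest negative ones those of miR-938 (−5.87), miR-504 (−5.59), miR-221 (−4.65) and miR-632 (−3.90). miR-1181 was below background at 48 h and miR-302d at 72 h, so their fitted differences (2.28 and −4.80) are not measured sizes, and only the bounds of at least 4.52-fold and 26-fold hold. Of the 20 probes called in opposite directions at both times, miR-504 went from 2.85 to −2.74, miR-938 from 2.15 to −3.73 and miR-221 from 1.89 to −2.76.

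Many probes went from background to bright signal or back in each comparison, although arrays of a group were nearly alike in r. Separate chance on each array is argued against by the lowest r within a group, 0.994, above the highest between groups, 0.943. That order does not hold on ranks, where dim probes weigh more. The rank correlation within a group was 0.848 for siCON and 0.859 for NFE2 siRNA, against 0.89 between the means of 48 h and 72 h of hemin. For dim probes, separate chance is thus not argued against. Opposite effects of more and less of a factor do not account for the whole pattern, with a mean r of −0.086 over the factors (−0.263, −0.151 and −0.067 with median scaling), though effects on single miRNAs are not excluded. Amplification of few molecules before the arrays was examined with miRNAs within 10 kb, over the pooled comparisons. The median difference in their changes was 1.222 times that of random pairs matched on level in the hemin comparisons (0.918 to 1.092 for 90% of random sets). In the others it was 1.157 (0.911 to 1.097), and without the large chromosome 14 cluster 1.16 and 1.245. Single comparisons ranged from 0.79 for NFE2 and 1.019 for GATA1 overexpression to 1.345 for NFE2 siRNA. The pooled values lay on the side set beforehand for amplification. Yet amplification, or processing of each miRNA apart from its neighbours, would let neighbours differ about as much as random pairs, not more. Random pairs were drawn afresh for each pair and comparison, whereas neighbours recur in several pairs and comparisons share control arrays. The range of the random sets may thus be too narrow, and it is not established that neighbours differed more than random pairs. The ratio does not decide between amplification and separate processing. Both remain open, as do different cultures or days for the groups.

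More probes fell in all 3 comparisons with a shared control than rose, 73 against 14 with pcDNA3.1 and 97 against 65 with siCON. For pcDNA3.1, untreated cells had a median position of 0.002 between the overexpressing groups (0) and the control (1), and 50 of the 73 lay nearer the groups. This lay on the side set beforehand for signal particular to the pcDNA3.1 arrays. The middle 50% of positions ran from −0.419 to 0.728, and untreated cells were unlike all the overexpression groups. The 14 probes that rose also had a median position of 0.002, with 9 nearer the groups. Probes picked for a control apart from all 3 groups can give such positions through the choice alone. The position therefore cannot separate signal particular to pcDNA3.1 from a response shared by the factors. For siCON the position was 0.324, with 55 of 97 nearer the siRNA groups, and signal particular to siCON cannot be told apart from effects shared by the siRNAs, as the position lay between the bounds set for either. A response shared by the 3 factors was not tested.

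All groups of the overexpression experiment were unlike untreated cells, with r of 0.366 for pcDNA3.1, 0.383 for EKLF, 0.273 for GATA1 and 0.393 for NFE2, so this is no trait of the pcDNA3.1 cells alone. Low total signal of the pcDNA3.1 arrays is argued against, since the dimmer siCON arrays correlated with untreated cells at 0.715 and 0.724 and the pcDNA3.1 arrays at 0.365, a gap of 0.349. Of the markers of other cell types, at most 33.3% of a list (3 of 9 neural and 1 of 3 liver) were at least 4-fold higher in pcDNA3.1, so cells of another type in the sample cannot be told apart from other sources with so few members. Transfection, culture and the day of each experiment are confounded with the groups and may each contribute.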

How the results depend on the processing

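The filter on probes detected on both arrays of both groups and the fit without the 3 dimmest groups were chosen after the results were seen. Of 6026 values of 412 named results under the alternatives, 5862 kept direction and side of the threshold, 69 lost the call, 43 gained it and 52 turned direction, the last all with median scaling, cyclic loess or the authors' table; the cause was not tested. Of these values, 101 were on miR-210 or miR-27a where both groups were below background, 6 of the gained and 6 of the turned ones among them, and no fold is given there. The named results include the largest changes of each comparison, and over all calls fewer were kept. Of the calls of a comparison, 54.8% (NFE2 siRNA) to 90.7% (hemin 72 h) were called in the same direction with median scaling, where GATA1 siRNA kept 63.9%, 56.5% to 89.1% with cyclic loess, 52.6% (GATA1 siRNA) to 93.0% in the authors' table and 80.1% to 99.6% with the experiment normalized alone. Median scaling called 124 of the 443 calls of GATA1 siRNA, 73 of the 418 of EKLF siRNA, 103 of the 508 of the GATA1 difference and 64 of the 522 of the EKLF difference in the other direction, and no more than 24 in another comparison. Signal over background limits the sizes: in each comparison, 72 to 168 of the calls were on probes below background in 1 group, for which only a bound can be given. Counts of calls moved by over 1.5 times with median scaling for 72 h against 48 h (573 against 328), EKLF (687 against 423) and GATA1 overexpression (675 against 310), siRNA against EKLF (795 against 418), GATA1 (827 against 443) and NFE2 (210 against 347) and the GATA1 difference (804 against 508), with cyclic loess for 72 h against 48 h (505) and NFE2 siRNA (221), and in the authors' table for GATA1 (289) and NFE2 siRNA (224); the cause was not tested. Only probes detected on both arrays of both groups gave 299 and 314 (hemin 48 h, 72 h), 250, 156 and 237 (EKLF, GATA1, NFE2 overexpression) and 191, 218 and 175 (siRNA), as fewer were tested. Of the 4 list calls, 0 remained with an estimated correlation and 2 with the stricter filter.

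With median scaling the log2 changes that turned were miR-210 (−0.41) at 48 h, miR-223 (−0.30) and miR-486-5p (−0.64) at 72 h, and miR-23a (−0.11) and miR-486-5p (−0.55) for 72 h against 48 h. They were miR-222 (0.36) for GATA1 and miR-23a (0.21) for NFE2 overexpression. With siRNA they were miR-16 (1.12), miR-223 (0.042), miR-24 (1.5) and miR-486-5p (0.024) for EKLF, miR-103 (0.77), miR-155 (−1.04), miR-221 (1.44), miR-23a (1.60) and miR-24 (0.79) for GATA1, and miR-23a (0.31) for NFE2. Cyclic loess turned miR-210 (−0.90) and miR-223 (−0.29) at 48 h, miR-210 (−0.37), miR-223 (−0.81), miR-24 (−1.18), miR-27a (−0.30) and miR-486-5p (−0.53) at 72 h, and miR-223 (−0.51), miR-23a (−0.45), miR-24 (−0.11), miR-451 (−0.086) and miR-486-5p (−0.40) between them. It also turned miR-486-5p (0.80) for EKLF overexpression, miR-144 (0.006) and miR-24 (0.58) for EKLF siRNA, miR-103 (0.73) and miR-23a (0.13) for GATA1 siRNA, and miR-486-5p (−1.0) for NFE2 siRNA. In the authors' table these were miR-210 (−0.34) at 48 h, miR-486-5p at 72 h (−0.23) and against 48 h (−0.22), miR-451 (−0.65) for GATA1 overexpression, miR-16 (0.25) and miR-24 (0.70) for EKLF siRNA, miR-103 (0.46), miR-221 (1.27), miR-23a (1.29) and miR-24 (0.52) for GATA1 siRNA and miR-486-5p (−0.29) for NFE2 siRNA. The cause was not tested. For miR-210, below background in both groups, the fitted values with median scaling and cyclic loess were 0.50 and 0.41 for EKLF overexpression, −1.12 and −0.78 for EKLF siRNA and −2.0 and −1.36 for GATA1 siRNA; they are no measured changes.

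With each array left out in turn, the lone array being assumed to vary like the other groups, the counts were 412 to 425 (48 h), 438 to 449 (72 h), 273 to 283 (72 h against 48 h), 368 to 415, 289 to 321 and 366 to 408 (EKLF, GATA1, NFE2 overexpression), 376 to 419, 370 to 428 and 361 to 376 (siRNA), and 481 to 523, 469 to 516 and 506 to 552 (differences). A replicate block gave 474, 495 and 331 calls for hemin and 437, 447 and 369 for siRNA and the same 4 list calls, and of the named results it changed only the call of miR-223 at 48 h (adjusted p = 0.054); deviations of same-numbered arrays correlated at 0.079 to 0.189 for hemin and 0.220 to 0.578 for siRNA, and 2 numbers per group are too few to tell whether the numbers pair the arrays. In every hemin and siRNA group array 1 had the higher mean signal, and all these correlations were positive. The array number may therefore mark a shared difference between arrays, which the main fit did not model. The authors' table gave no value for NFE2 overexpression and its difference, since its columns are copies, and a block on the chip was not run.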

Other observations

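The counts and the miRNAs named in this part were chosen after the results were seen, and the counts were made in the main fit only. Of the 198 probes higher at both hemin times, 23 also rose on EKLF overexpression and fell with EKLF siRNA (13.2 if independent), among them miR-22. For GATA1 they were 17 (8.9 if independent) and for NFE2 16 (8.2). Of the 181 lower at both times, 13 fell on EKLF overexpression and rose with EKLF siRNA (9.2 if independent), 21 did so for GATA1 (8.4) and 32 for NFE2 (10.5). The contrary patterns were also present. Probes higher with hemin that fell on overexpression and rose with siRNA numbered 12 for EKLF (10 if independent), 6 for GATA1 (9.2) and 11 for NFE2 (11.5), and those lower with hemin that rose and fell numbered 21 (12), 8 (8.1) and 15 (7.5). In the first patterns, pairs of unlike factors gave 14 to 17 (6.2 to 14.5 if independent) and 17 to 26 (7.4 to 12), and in the contrary ones 6 to 12 (8 to 13.1) and 6 to 27 (5.6 to 13.3), the 27 for EKLF overexpression with GATA1 siRNA. By count alone, EKLF among the probes higher and NFE2 among those lower with hemin lay above the ranges of the first patterns. EKLF among those lower (13) lay below its range. The counts expected if independent differ between pairs, so the counts alone do not set a factor apart. GATA1 overexpression with NFE2 siRNA, a pair of unlike factors, gave 14 (6.2 if independent) and 23 (7.4). No difference between pairs was tested.

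Some probes were detected on both arrays of 1 group and on no other array. Such counts also depend on how many probes a group detected on both arrays. That number was 649 at 72 h, 573 at 48 h, 489 for NFE2 overexpression, 383 for siCON and 345 for NFE2 siRNA. None of the probes found only at 72 h or only with NFE2 overexpression had a group mean above log2 10. The probes found in a single group numbered 22 for NFE2 overexpression (miR-34b and miR-214 among them), 15 at 72 h of hemin (miR-125b, miR-99a and miR-218), 9 for GATA1 overexpression (miR-217), 9 for pcDNA3.1 (miR-203), 8 for EKLF siRNA (miR-208a), 7 at 0 h (miR-518f), 5 at 48 h, 4 for EKLF overexpression (miR-562), 4 for GATA1 siRNA (miR-513b), 1 for siCON (miR-520g) and 1 for NFE2 siRNA.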
